A study of Mus musculus with 6 samples.

How the data were processed

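Total RNA of intermediate and outer interzone from mouse embryos at 15.5 days of gestation was profiled with 3 arrays per group, and 1 replicate was 1 embryo, per the labels. RNA was extracted with a kit for small samples, amplified and labelled with Cy3 using a low-input kit, per the labels' protocols, and how the layers were separated is not given in the sources used here. The arrays were read with Agilent Feature Extraction 10.7.3.1, per the file headers, and the submitters' processing notes also name Partek 6.11.0321 without saying which step it served. Each deposited scanner file gives, per the file headers, a processed signal intensity per spot, with the background subtracted and trends over the array removed, the mean and local background intensity, and flags for spots that are saturated, outliers or not well above background. The authors' deposited table of the whole series holds an intensity on a linear scale for the same spots. Each of its columns has a median of 1 and equals the scanner file's processed signal divided by 1 constant per array (spread of that constant at most 0.000785%), so the authors' values are the processed signals scaled to each array's median. They are neither log-transformed nor centred per gene, and the direction of any comparison by the authors is not stated. Probe positions and names come from the files, which use build mm9.

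The scanner files hold 59305 non-control spots for 55681 probes. Spots of one probe were averaged on the log2 scale with flagged spots left out, and 9 probes without a value on some array were dropped. Of 28390 probes with a RefSeq accession, 26762 were matched to a symbol in a RefSeq table of a later assembly, which changed 2878 symbols, and other probes kept the name in the files. The later table served only for names. Printed positions are those of the probe, and exon and UTR annotation was not used here. The log2 processed signal minus each array's 75th percentile was the main value. A probe was tested where it was well above background on all 3 arrays of at least 1 group, which left 23885 probes. Each gene was represented by its brightest tested probe, which gave 18004 genes. Of 144 called genes with several tested probes, 5 had probes whose differences had opposite signs.

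Outer and intermediate interzone were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p 0.05. Where a gene's probe was not well above background on any array of a group, the fold is a bound, the bright group's mean against, per array of the dim group, the higher of the probe's own value and the lowest signal among probes well above background. There were 23 gene lists, fixed before the data were examined, on cartilage, joint, tendon, bone, signalling pathways and the markers of other cell types that limb tissue holds. They were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 23 lists. No measured gene is in more than 1 list. The named genes follow a rule fixed at the same time. It takes the 12 genes with the largest difference in each direction among the called genes that have a gene symbol and whose groups did not overlap, 18 genes of cartilage, joint and tendon, and from each list up to 4 called members with the largest difference, or the 2 brightest where none was called. It gave 96 genes with a test. Col10a1 and Ihh belong to it and were not tested.

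The replicate numbers come from the labels, which do not say that the same number marks the same embryo. After subtracting group means, same-numbered samples correlated at 0.563, 0.480 and 0.371 across genes for replicates 1, 2 and 3, above every correlation between different numbers, of which the highest was 0.114. The numbers may thus pair the samples. With group means removed, a positive correlation with 1 sample of the other group forces lower ones with the rest. The values between different numbers are therefore no independent reference. The main fit was set without a block, so its SEs, intervals and p-values ignore any pairing. The fit with the replicate number as a block is an alternative, given where it changes the call of a list or of a named gene. Slide 1 held 3 intermediate and 1 outer array and slide 2 held 2 outer arrays, all scanned on 1 day, so slide was fitted as a block and slide 1 was also fitted alone. In both of these the difference rests on outer replicate 1, the dimmest array, and within slide 1 its spread is assumed to be that of the intermediate arrays. Each array's signal over background sets which genes could be measured, and the 3 arrays per group limit the precision of every difference.

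The other alternatives were quantile normalization, scaling to the median, the authors' deposited values, normexp background correction (offset 50) with quantile normalization, no filter and a filter on all 6 arrays, the mean of a gene's probes or every probe counted, an unmoderated test, eBayes with trend and robust settings, array weights, thresholds of 2-fold or adjusted p 0.10, and leaving out each array in turn. The normexp offset exceeds the median processed signal of every array (4.32 to 20.7). It therefore shrinks the log2 differences of dim genes by construction. Added after seeing the data were quantile normalization with the replicate block, and both blocks together, the gaps between cell type markers paired by replicate number, and the size of the named genes' differences with normexp. With both blocks together, slide takes up the other pairs, and the difference is that of outer and intermediate replicate 1 alone. The fit was tested on simulated data drawn from each gene's mean and residual SD over the 18004 genes of this comparison, 20 times with 200 genes changed. It recovered 26.6% of genes changed 2-fold, 73.1% of those changed 4-fold and 89.3% of those changed 8-fold, none with the wrong sign, and 5.66% of all calls were false. In the same simulations camera found 20 of 20 lists of 20 genes shifted 2-fold and called 0 of 440 unchanged lists. The simulated genes were independent of each other, which real genes are not. Every simulated array had the same spread for a gene, without pairing by number. The real arrays were unequal, with limma array weights from 0.39 (outer replicate 1) to 4.33 (outer replicate 3). These rates may therefore not hold for the real arrays.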

Results

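The interzone is the band of condensed cells that marks a future synovial joint between the cartilage templates of a developing limb. Its outer layers lie against the cartilage, and its intermediate layer lies between them. Gene expression of the intermediate and the outer interzone was measured in mouse embryos at 15.5 days of gestation, with 3 samples of each, and each replicate was 1 embryo. Cy3-labelled cRNA made from total RNA was hybridised to 6 one-colour Agilent whole-genome arrays. The 75th percentile of the processed signal was 144, 265 and 344 on the intermediate arrays (replicates 1, 2 and 3) and 47.4, 290 and 150 on the outer arrays. The outer replicate 1 array was thus the dimmest, with 35.6% of its spots well above background against 45.1% to 53.4% on the other 5. No spot was saturated. Levels are given as log2 signal over the 75th percentile of the same array, with SD over n = 3 arrays, and differences as outer minus intermediate.

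Cartilage genes were higher in the outer interzone samples, and genes of leukocytes and blood vessels were higher in the intermediate interzone samples. How the layers were separated is not given, so the share of neighbouring tissue in the samples of either group is not known. Of 18004 genes tested, limma called 729 at adjusted p 0.05, 282 of them higher in the outer and 447 higher in the intermediate interzone, and the samples of the groups did not overlap for any of the 729. Over all genes, 27.1% had groups that did not overlap. Chance gives 10% if the 6 arrays are independent of each other, which same-numbered samples did not appear to be. Of the called genes, 674 differed at least 2-fold. All 3 outer arrays and all 3 intermediate arrays measured 221 of the genes higher in the outer interzone and 187 of those higher in the intermediate interzone. Another 137 of the latter were well above background on 2 outer arrays, 97 on 1 and 26 on none. Requiring signal on all 6 arrays gave 460 calls, 247 higher in the outer and 213 higher in the intermediate interzone, of which 409 were among the 729. The median of all genes lay at 0.10, and scaling each array to its median, as in the authors' deposited values, moved it to -0.29 and the calls to 158 higher in the outer and 938 higher in the intermediate interzone.

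The number of calls rested on single arrays and on the design of the fit. Without intermediate replicates 1, 2 and 3 in turn, limma called 137, 381 and 66 genes, without outer replicates 2 and 3 it called 1111 and 90, and without the dim outer replicate 1 it called 583. Same-numbered outer and intermediate samples deviated together, and with the replicate number as a block limma called 1636 genes, 836 of them higher in the outer interzone, but 68 (47 and 21) with that block on quantile-normalized values. Without a filter on dim probes limma called 0 genes, with 4268 at unadjusted p under 0.05, and the unmoderated test gave 0, with 3251. One slide held the 3 intermediate arrays and outer replicate 1, and the other slide held only outer arrays. With slide as a block, 1215 genes were called, 481 higher in the outer and 734 higher in the intermediate interzone, and within the shared slide 1314 were called, 518 and 796. Of the 729 genes, 681 were called again with the replicate block, 484 with the slide block and 290 with both blocks together. Their direction could not change in these fits, since the groups did not overlap for any of the 729. With both blocks together, the difference rests on the replicate 1 samples alone, which include the dim outer array.

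The 12 genes with the largest difference toward the outer interzone included 7 from the lists on cartilage, its regulators and hedgehog signalling. Cytl1, which encodes a secreted protein of cartilage, reached 5.74 ± 1.21 (SD, n = 3) in the outer and -0.17 ± 0.75 in the intermediate interzone, a difference of 5.91 with SE 0.64 (limma adjusted p = 0.00914; probe at chromosome 5, 38130789 to 38130848, mm9). Ucma, a Gla protein of resting cartilage, differed by 6.50 (adjusted p = 0.0159; chromosome 2, 4906712 to 4906771), the cartilage matrix protein gene Matn1 63.9-fold (adjusted p = 0.0182; chromosome 4, 130511217 to 130511276) and the proteoglycan gene Snorc by 5.85 (adjusted p = 0.00741; chromosome 1, 89371962 to 89372021), each in limma. These 3 were well above background on 1 of the 3 intermediate arrays, so the size of their differences is uncertain, and with normexp background correction Ucma, Matn1 and Snorc differed by 3.77, 2.34 and 2.48. Gli1, a transcription factor and target of hedgehog signalling, differed by 5.51 with SE 0.75 (limma adjusted p = 0.0168; chromosome 10, 126766967 to 126767026). Pthlh, the gene of a secreted hormone-like protein that holds back chondrocyte maturation, differed by 4.92 (limma adjusted p = 0.0153; chromosome 6, 147200926 to 147200985), with 1 of 3 intermediate arrays above background. Susd5, of the cartilage matrix list, and Ncmap were measured on all 6 arrays and differed by 5.01 and 4.98 (limma adjusted p = 0.0022 for both). Meltf, a transferrin-like protein, and Pdcd1, known as an immune checkpoint receptor, differed by 5.63 and 5.45, with 1 of 3 intermediate arrays above background, and by 3.14 and 2.43 with normexp, where Pthlh differed by 2.67. Tctex1d1 and the noncoding Pantr1 were not well above background on any intermediate array and were at least 9.66-fold and 9.63-fold higher in the outer interzone on the main scale (limma adjusted p = 0.00438 and 0.00741), and differed by 1.34 and 1.36 with normexp, below these bounds. With slide as a block Matn1 lost its call (difference 5.30, limma adjusted p = 0.0517).

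Cartilage matrix genes as a group were higher in the outer interzone. Of 29 measured genes, 19 were higher in the outer interzone, 1 was higher in the intermediate interzone and 9 did not pass. Adjusted over the list alone, the counts were 21 and 3. Col2a1, the main fibrillar collagen of cartilage, stood at 8.87 ± 0.35 (SD, n = 3) in the outer and 5.68 ± 0.67 in the intermediate interzone, 9.15-fold higher in the outer (limma adjusted p = 0.011). The link protein gene Hapln1 was 8.80-fold higher (limma adjusted p = 0.00741) and aggrecan (Acan) 2.23-fold higher (limma adjusted p = 0.0182). The exception was Epyc, a small leucine-rich proteoglycan, at -2.54. The median of the list was 2.34, or 2.24 above that of all genes (camera adjusted p = 3.09e-12; adjusted p = 0.103 with an estimated correlation), and with slide as a block it was 2.86. The per-array list means separated the groups, at 2.99 ± 0.13 (SD, n = 3) in the outer and 0.61 ± 0.27 in the intermediate interzone.

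**Figure D1:**
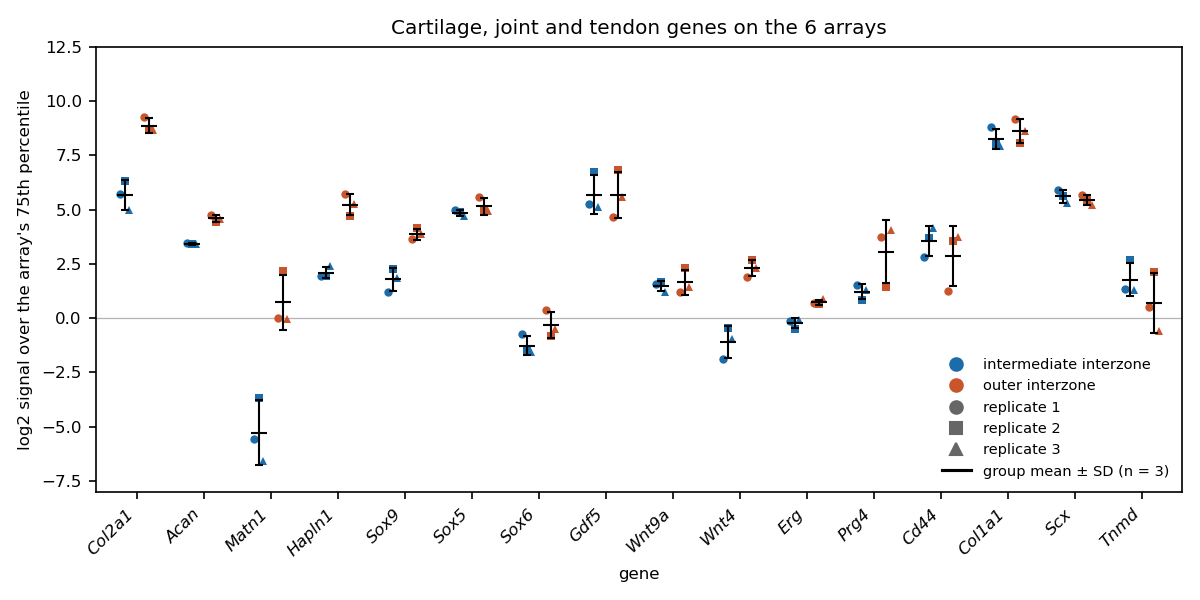
Levels of 16 genes of cartilage, joint and tendon, as log2 signal over the 75th percentile of each array (vertical axis), with 1 symbol per array and bars for the group mean and SD (n = 3). Col2a1, Acan, Matn1, Hapln1, Sox9, Wnt4 and Erg separate the groups and pass limma's adjusted p of 0.05, whereas Gdf5 lies at 5.69 in both groups.

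Chondrogenic regulators moved the same way. Of 17 measured, 5 were higher in the outer interzone and 12 did not pass, and adjusted over the list alone 7 were higher. Sox9, the transcription factor that cartilage formation requires, was 4.26-fold higher in the outer interzone (limma adjusted p = 0.0176; adjusted p = 0.0481 with slide as a block, call lost within the shared slide). Fgfr3, a receptor that limits chondrocyte proliferation, was 11.4-fold higher (limma adjusted p = 0.00438) and the ubiquitin ligase gene Wwp2, host of a cartilage microRNA, 4.29-fold higher (limma adjusted p = 0.00741). Sox5 and Sox6, the partners of Sox9, did not pass, at 0.29 (limma adjusted p = 0.511) and 0.96 (limma adjusted p = 0.195, and 0.0366 with the replicate block). The list median was 0.84, or 0.74 above all genes (camera adjusted p = 0.000826; adjusted p = 0.103 with an estimated correlation), and 0.73 with slide as a block. Genes of hypertrophic chondrocytes were largely not measurable, with 13 of 19 not tested. Col10a1 and Ihh, markers of hypertrophic and prehypertrophic cartilage, were not well above background on any of the 6 arrays. Among the 6 measured, Vegfa was higher in the outer interzone (0.89, limma adjusted p = 0.0491) and Pdlim1 lower (-1.24, limma adjusted p = 0.0203), 3 and 1 passed when adjusted over the list alone, and the list was not shifted (camera adjusted p = 0.615). Vegfa lost its call with slide as a block (adjusted p = 0.0524).

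Hedgehog target genes were higher in the outer interzone. Of 14 measured genes of the pathway list, 4 were higher in the outer interzone (6 when adjusted over the list alone) and none was lower. Besides Gli1, these were Hhip (3.56), Ptch1 (3.16) and Foxc2 (1.85), with limma adjusted p = 0.00433, 0.00741 and 0.00673. Hhip and Ptch1, a decoy and a receptor for hedgehog ligands, are induced by the pathway. Hedgehog genes had a median of 0.54, or 0.44 above all genes (camera adjusted p = 0.000311; adjusted p = 0.194 with an estimated correlation), and 0.51 with slide as a block. Of 36 measured genes of the Wnt list, 8 were higher in the outer and 1 in the intermediate interzone, or 10 and 3 when adjusted over the list alone. Several of the 8 encode secreted inhibitors, namely Sfrp5 (4.29, limma adjusted p = 0.00516), Sostdc1 (4.23, limma adjusted p = 0.00889), Frzb (2.95) and Wif1 (3.04), and another is the R-spondin receptor gene Lgr6 (3.28, limma adjusted p = 0.0217). Sfrp5 was well above background on 2 of 3 intermediate arrays and differed by 1.98 with normexp. Rspo2, which encodes a secreted enhancer of Wnt signalling, was 8.51-fold higher in the intermediate interzone (limma adjusted p = 0.012). Wnt genes had a median of 0.44, or 0.34 above all genes (camera adjusted p = 0.00592; adjusted p = 0.396 with an estimated correlation), and 0.31 with slide as a block. The call ended with the filter that required signal on all 6 arrays (camera adjusted p = 0.052) and without any filter (camera adjusted p = 0.132).

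Genes that mark the early joint did not shift as a group. Of 25 measured, 3 were higher in the outer interzone and 1 in the intermediate interzone, and with the replicate block 4 and 3 were called. Adjusted over the list alone, 6 and 2 were called. Gdf5, the growth factor gene that marks interzone cells, was abundant in both layers, at 5.69 ± 1.07 (SD, n = 3) in the outer and 5.69 ± 0.89 in the intermediate interzone (limma adjusted p = 0.998; 95% interval of the difference -1.48 to 1.47). Wnt9a differed by 0.16 (limma adjusted p = 0.806). Wnt4 was 10.6-fold higher in the outer interzone (limma adjusted p = 0.011), Bmp2 3.83-fold (limma adjusted p = 0.0182) and the transcription factor Erg 1.93-fold (limma adjusted p = 0.0417, and 0.0952 with slide as a block). Gdf6, a close relative of Gdf5, was 3.40-fold higher in the intermediate interzone (limma adjusted p = 0.0167), with 2 of 3 outer arrays above background and a difference of -1.01 with normexp. The list median was -0.00, or -0.10 relative to all genes (camera adjusted p = 0.911), and -0.28 with slide as a block. Bmp2 lost its call within the shared slide.

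Genes of the articular surface and synovium were shifted toward the intermediate interzone. Of 15 measured, 2 passed, both higher in the intermediate interzone, and 6 passed when adjusted over the list alone. They were Fndc1 (-2.77, limma adjusted p = 0.0256) and Sparcl1, a matrix glycoprotein of the SPARC family (-1.64, limma adjusted p = 0.0459). Fndc1 lost its call with slide as a block (adjusted p = 0.0629) and Sparcl1 with the replicate block (adjusted p = 0.0578). Prg4, the gene of lubricin, the lubricant of the joint surface, went the other way without passing, at 3.07 ± 1.44 (SD, n = 3) in the outer and 1.23 ± 0.35 in the intermediate interzone (limma adjusted p = 0.18), and it was called within the shared slide. Cd44, the hyaluronan receptor gene, stood at 2.86 ± 1.39 and 3.56 ± 0.68 (limma adjusted p = 0.598), and with slide as a block it was lower in the outer interzone (-2.30, adjusted p = 0.0425). The list median was -0.51, or -0.61 relative to all genes (camera adjusted p = 0.0138; adjusted p = 0.154 with an estimated correlation). The call ended with slide as a block (median -0.54, camera adjusted p = 0.073), within the shared slide (camera adjusted p = 0.12) and without outer replicate 2 (median -0.39, camera adjusted p = 0.0821).

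Few fibrous tissue genes differed between the layers. Of 20 tendon and ligament genes measured, 1 passed, Eya2, at -2.38 (limma adjusted p = 0.0316, and 0.0541 with slide as a block). Scx, the transcription factor of tendon progenitors, differed by -0.17 (limma adjusted p = 0.705) and its target Tnmd by -1.09 (limma adjusted p = 0.419). Adjusted over the list alone, 1 passed as well. None of 12 bone and perichondrium genes passed, 1 was lower when adjusted over the list alone, and limma called 2 of them with the replicate block, both higher in the intermediate interzone. Col1a1 differed by 0.39 (limma adjusted p = 0.561), Sparc by 0.20 and Col1a2 by 0.07. The list medians were -0.15 and -0.27, or -0.25 and -0.37 relative to all genes (camera adjusted p = 0.0804 and 0.0842), and -0.14 and 0.05 with slide as a block. With the replicate block both lists passed toward the intermediate interzone (camera adjusted p = 0.0176 and 0.0382), as they did without a filter (camera adjusted p = 0.000421 and 0.00168). The tendon list also passed with normexp, with signal required on all 6 arrays, without intermediate replicate 3 and with both blocks (camera adjusted p = 0.043, 0.0383, 0.0358 and 0.016), and the bone list without intermediate replicate 2 or outer replicate 1 (camera adjusted p = 0.0293 and 0.0154). The fit with both blocks rests on the replicate 1 samples.

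**Figure D2:**
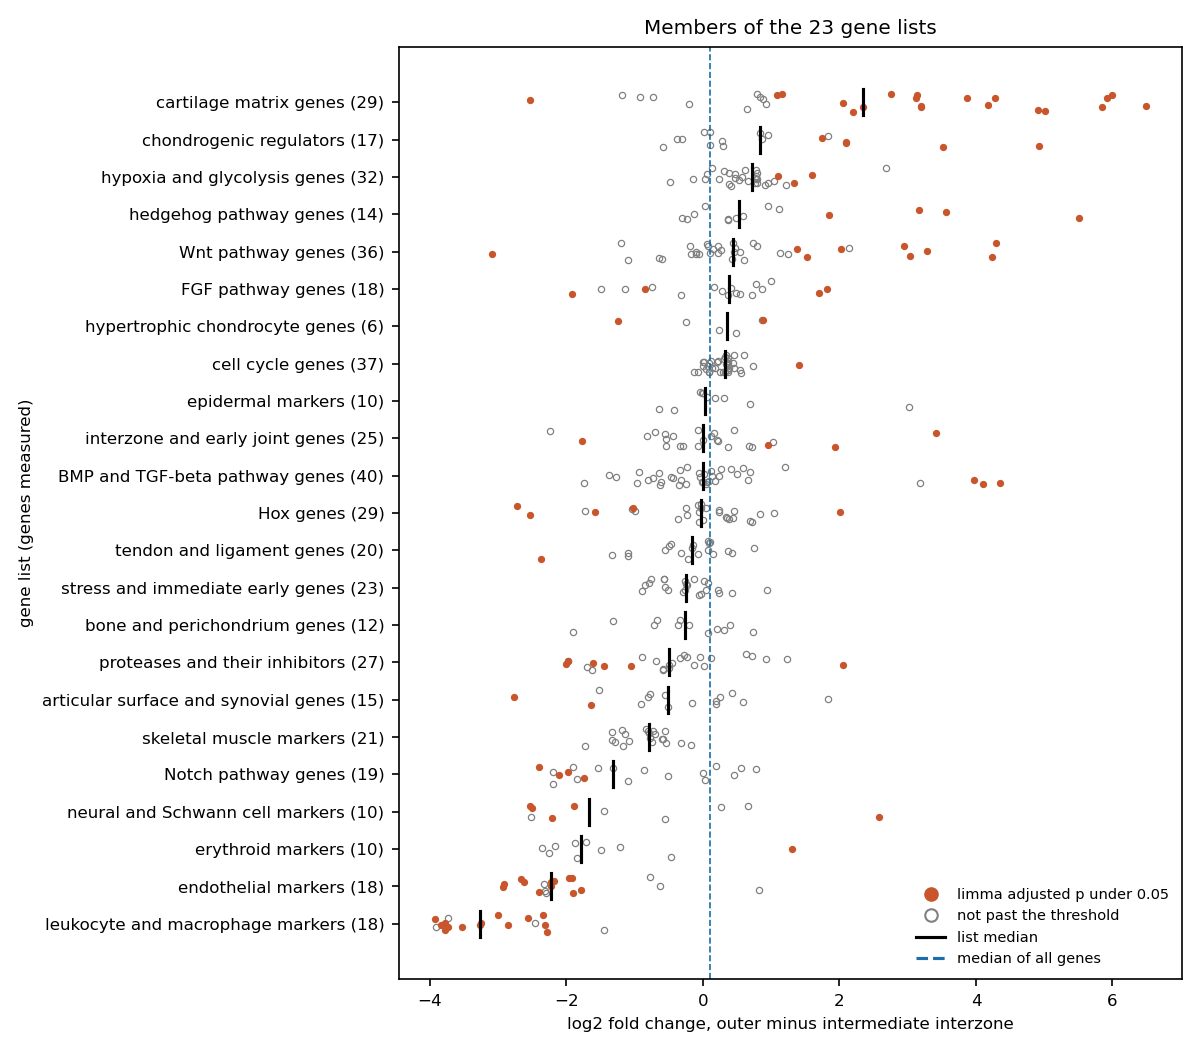
Difference between outer and intermediate interzone for each measured gene of the 23 lists (horizontal axis, log2; 1 point per gene, lists on the vertical axis ordered by median, number of genes in brackets). Filled points passed limma's adjusted p of 0.05, black bars are list medians, and the dashed line is the median of all genes at 0.10. Cartilage matrix genes have the highest median, at 2.34, and leukocyte markers the lowest, at -3.26.

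Leukocyte and endothelial markers were lower in the outer interzone. Of 18 leukocyte and macrophage markers, 14 were lower and 4 did not pass, and all 18 were lower when adjusted over the list alone. The fractalkine receptor gene Cx3cr1 stood at 3.83 ± 0.62 (SD, n = 3) in the intermediate and -0.10 ± 1.63 in the outer interzone, 15.3-fold lower in the outer (limma adjusted p = 0.0437). The mannose receptor gene Mrc1 was 14.2-fold lower, the complement gene C1qa 13.7-fold lower and the macrophage surface marker gene Adgre1 13.7-fold lower (limma adjusted p = 0.0382, 0.0241 and 0.0311). Of the 3 outer arrays, 2 measured each of these 4. Cx3cr1, Mrc1 and C1qa were among the 12 genes with the largest difference toward the intermediate interzone, and the other 9 are in none of the lists, among them Vav1 (-3.92), Ms4a7 (-3.88), Ccl9 (-3.86), Ctss (-3.79) and Lyve1 (-3.78). Folr2 and Ms4a4a were measured on 1 outer array, differed by -1.91 and -1.66 with normexp and lost their calls with slide as a block and with the replicate block, and Ms4a7 with the replicate block alone. The receptor gene Pirb and the homeobox gene Evx1 were not well above background on any outer array and were at least 7.18-fold and 4.60-fold higher in the intermediate interzone on the main scale (limma adjusted p = 0.0174 and 0.0159). With normexp they differed by -1.67 and -1.24, below these bounds, and Pirb lost its call within the shared slide. Leukocyte markers had a median of -3.26, or -3.36 relative to all genes (camera adjusted p = 2.99e-20; adjusted p = 0.14 with an estimated correlation), and -4.09 with slide as a block. The list includes Lyz1 and Lyz2, near-identical copies whose probes may share signal.

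Of 18 endothelial markers, 12 were lower in the outer interzone and 6 did not pass. Adjusted over the list alone, 17 were lower and 1, Kdr, was higher. Flt1, a VEGF receptor gene measured on all 6 arrays, was 6.18-fold lower (limma adjusted p = 0.0341). Emcn, Tek and Tie1 were 7.62-fold, 7.56-fold and 6.35-fold lower (limma adjusted p = 0.00811, 0.00907 and 0.0167), with 2, 1 and 2 of the 3 outer arrays above background, and with normexp background correction they differed by -2.08, -1.23 and -1.88. Endothelial markers had a median of -2.22, or -2.32 relative to all genes (camera adjusted p = 1.74e-16; adjusted p = 0.14 with an estimated correlation), and -3.04 with slide as a block. Erythroid and skeletal muscle markers were lower in the outer samples by camera as well, at medians of -1.78 and -0.79 (camera adjusted p = 0.0465 and 0.00541; adjusted p = 0.623 for both with an estimated correlation), but no muscle gene passed, also when adjusted over the list alone, and the erythroid gene that passed was higher in the outer interzone, namely the transferrin receptor gene Tfrc (1.31, limma adjusted p = 0.0311, call lost within the shared slide and with normexp). In each same-numbered pair both list means were lower in the outer sample, and the replicate block kept both calls (camera adjusted p = 0.000788 and 6.11e-07). Without outer replicate 1, the dim array, the medians were -0.39 and 0.32 (camera adjusted p = 0.478 and 0.776), and with slide as a block, where that array alone stands for the outer interzone, they were -4.45 and -2.82. Leaving out intermediate replicate 3 also ended both calls (camera adjusted p = 0.128 and 0.136), and leaving out intermediate replicate 2 ended the erythroid call (camera adjusted p = 0.114), as did quantile normalization alone (camera adjusted p = 0.0974) or after normexp (camera adjusted p = 0.0541). The brightest muscle genes, Tnni2 and Actc1, differed by -0.55 and -1.14 (limma adjusted p = 0.384 and 0.708). The globin genes of the erythroid list are near-identical copies, so their separate values are uncertain.

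**Figure D3:**
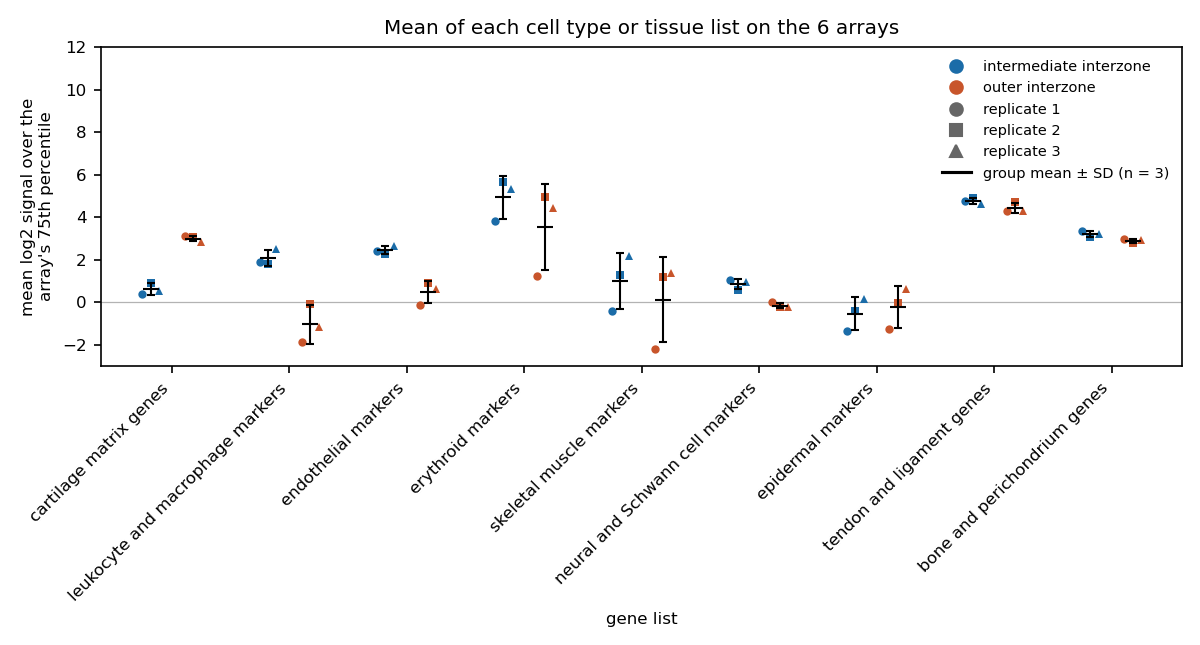
Mean log2 signal over the 75th percentile (vertical axis) of 9 cell type or tissue lists on each of the 6 arrays, with 1 symbol per array and bars for the group mean and SD (n = 3). Leukocyte markers average 2.07 in the intermediate and -1.04 in the outer samples without overlap, whereas muscle and erythroid markers vary widely within each group and are lowest on the outer replicate 1 array, at -2.18 and 1.22.

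Notch pathway genes and proteases were lower in the outer interzone together with the endothelial and leukocyte markers, whose list medians were -2.22 and -3.26. Of 19 Notch genes, 4 were lower in the outer interzone, 15 did not pass, and the counts were 10 lower and 2 higher when adjusted over the list alone. The 4 were Nrarp (-2.40, limma adjusted p = 0.00673), Notch4, a receptor of endothelial cells (-2.10, limma adjusted p = 0.0378), and the Fringe genes Mfng (-1.98, limma adjusted p = 0.0314) and Lfng (-1.74, limma adjusted p = 0.0334, lost with either block and with normexp). Notch4 was measured on 2 outer arrays, and Nrarp (-0.84 with normexp) and Lfng on 1. With the replicate block 7 were lower and 1 higher. Notch genes had a median of -1.32, or -1.42 relative to all genes (camera adjusted p = 2.92e-05; adjusted p = 0.356 with an estimated correlation), and -1.48 with slide as a block. Where signal was required on all 6 arrays, it was -0.00 and the call ended (camera adjusted p = 0.0902). Of 27 proteases and inhibitors, 5 were lower in the outer interzone, 1 was higher, and 9 and 1 passed when adjusted over the list alone. Adamts2, which trims procollagen, was 4.02-fold lower (limma adjusted p = 0.0286), the urokinase gene Plau 3.96-fold lower (limma adjusted p = 0.0176, 1 outer array above background, -0.82 with normexp) and the aggrecanase gene Adamts4 3.06-fold lower (limma adjusted p = 0.0465, and 0.0765 with slide as a block). Adamts17 was 4.15-fold higher (limma adjusted p = 0.0291, and 0.0743 with slide as a block). Proteases had a median of -0.49, or -0.59 relative to all genes (camera adjusted p = 0.00025; adjusted p = 0.103 with an estimated correlation), and -0.52 with slide as a block.

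Among 10 neural and Schwann cell markers, 4 were lower and 1 was higher in the outer interzone, or 6 and 1 when adjusted over the list alone. The neurofilament genes Nefl and Nefm were 5.78-fold and 5.65-fold lower and the growth cone gene Gap43 4.63-fold lower (limma adjusted p = 0.00503, 0.00818 and 0.0242). Nefm was above background on 2 of 3 outer arrays and differed by -1.32 with normexp. S100b, also expressed in cartilage, was higher by 2.59 (limma adjusted p = 0.0182). Neural markers had a median of -1.67, or -1.77 relative to all genes (camera adjusted p = 0.000355; adjusted p = 0.103 with an estimated correlation), and -1.35 with slide as a block. Of 10 epidermal markers none passed and the median was 0.03 (camera adjusted p = 0.896), or -0.99 with slide as a block. The brightest were Trp63, at 0.69 (limma adjusted p = 0.399), and Krt17, at 3.02 (limma adjusted p = 0.165), which passed with the replicate block (adjusted p = 0.0270).

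Single BMP, FGF and Hox genes differed between the layers, and their lists were not shifted in the main fit. Of 40 BMP and TGF-beta genes, 3 were higher in the outer interzone, namely Id4 (4.36, limma adjusted p = 0.00741), Bmper (4.10, limma adjusted p = 0.0311) and Bmp5 (3.97, limma adjusted p = 0.00433), each on 2 of 3 intermediate arrays above background and with differences of 2.36, 2.61 and 1.83 with normexp. The same number passed when adjusted over the list alone, and with the replicate block 4 were higher and 2 lower. Bmper lost its call with slide as a block (adjusted p = 0.0502). Of 18 FGF genes, Fgfrl1 (1.82) and Fgfr2 (1.70) were higher in the outer interzone and Fgf9 (-1.92) and Spry1 (-0.85) lower (limma adjusted p = 0.0184, 0.0159, 0.048 and 0.0456). Adjusted over the list alone 4 and 4 passed, with the replicate block 4 and 3, and Spry1 lost its call with slide as a block (adjusted p = 0.0523). Of 29 Hox and limb patterning genes, 4 were lower, among them Hoxb7 (-2.73), Hoxb4 (-2.53) and Hoxb2 (-1.59), with limma adjusted p = 0.0169, 0.00741 and 0.0263, and Shox2 was higher (2.01, limma adjusted p = 0.047). Adjusted over the list alone, 6 were lower and 3 higher. The 3 HoxB genes were well above background on 2, 1 and 1 of the outer arrays and differed by -1.38, -0.92 and -0.55 with normexp, where Hoxb2 lost its call, and Hoxb2 and Shox2 lost their calls with slide as a block (adjusted p = 0.0581 and 0.0701). The medians of the 3 lists were -0.00, 0.39 and -0.02, or -0.10, 0.29 and -0.12 relative to all genes (camera adjusted p = 0.369, 0.369 and 0.32), and -0.17, 0.24 and -0.27 with slide as a block. Camera called the BMP list with signal required on all 6 arrays (median -0.05, adjusted p = 0.00828) and without a filter (median -0.00, adjusted p = 0.00425), and the Hox list without a filter (median -0.02, adjusted p = 0.00305) and, toward the outer interzone, with signal required on all 6 arrays (median 0.35, adjusted p = 0.0459).

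Hypoxia and glycolysis genes were higher in the outer interzone. Of 32 measured, 30 had a positive difference, 3 passed (14 when adjusted over the list alone, and 10 with the replicate block) and none was lower. Bnip3, a hypoxia-induced mitophagy gene, was 3.02-fold higher, Ankrd37 2.53-fold and the collagen prolyl hydroxylase gene P4ha2 2.14-fold (limma adjusted p = 0.0341, 0.0193 and 0.0174), and P4ha2 lost its call within the shared slide. Hypoxia genes had a median of 0.71, or 0.61 above all genes (camera adjusted p = 4.69e-07; adjusted p = 0.292 with an estimated correlation), and 0.73 with slide as a block. Of 37 cell cycle genes, 1 passed, also when adjusted over the list alone, the cyclin gene Ccnd1, 2.65-fold higher in the outer interzone (limma adjusted p = 0.0179, and 0.0519 with slide as a block). The other 36 lay close together, and the list median was 0.32, or 0.22 above all genes (camera adjusted p = 0.00557; adjusted p = 0.623 with an estimated correlation). The call ended with slide as a block (median 0.22, camera adjusted p = 0.198), without outer replicate 2 (camera adjusted p = 0.225) and without a filter (camera adjusted p = 0.19). None of 23 stress and immediate early genes passed, and the brightest, Jund and Dnajb1, differed by 0.04 and 0.01. Their median of -0.25 was -0.34 relative to all genes (camera adjusted p = 0.0216; adjusted p = 0.582 with an estimated correlation) and -0.48 with slide as a block, and the call ended without outer replicate 1 (camera adjusted p = 0.149) or intermediate replicate 2 (camera adjusted p = 0.0547).

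In all, camera called 15 of the 23 lists, 6 toward the outer and 9 toward the intermediate interzone. None of the 15 passed with an estimated correlation, where the lowest adjusted p was 0.103, and 10 passed with fry, which tests whether the genes of a list move one way without comparing them with other genes. Of the 96 named genes limma called 79. With normexp all kept their direction. Its offset of 50 shrinks the differences of dim genes by construction. The 37 of the 79 that were not above background on all 6 arrays had a median of 0.527 of their main log2 difference, against 0.847 for the other 42. With the replicate block 74 of these were called again, and with slide as a block and within the shared slide 64 each. Leaving out each array in turn, 20 of the 79 were called in all 6 fits. They included Col2a1, Hapln1, Snorc, Susd5, Fgfr3, Wwp2, Ptch1, Hhip, Sfrp5, Bmp5 and Id4 among those higher in the outer interzone. The only ones higher in the intermediate interzone were Nefl, Nrarp and Hoxb4. No named member of the leukocyte or endothelial list was called in all 6 fits.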

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

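Quantile normalization with the replicate block, and both blocks together, were chosen after the result was seen. The count of called genes moved with the processing. Against 729 genes (282 higher in the outer, 447 higher in the intermediate interzone), the replicate block gave 1636 (836 and 800), slide as a block 1215 (481 and 734), slide 1 alone 1314 (518 and 796), quantile normalization 455 (166 and 289), scaling to the median and the authors' deposited values, which are the same scaling, 1096 (158 and 938), the filter on all 6 arrays 460 (247 and 213), array weights 3994 (2302 and 1692) and adjusted p 0.10 1421 (629 and 792). Leaving out 1 array at a time gave 66 to 1111 (46 to 489 and 20 to 622). The lowest count came without intermediate replicate 3, and intermediate replicates 1 and 2 and outer replicates 2 and 3 also moved it by over 1.5 times, to 137, 381, 1111 and 90. Quantile normalization with the replicate block gave 68 (47 and 21). Both blocks together, where the difference rests on the replicate 1 samples, gave 701 (294 and 407), of which 290 were among the 729. Without a filter on dim probes, limma called 0 genes (0 and 0), and the unmoderated test gave 0 (0 and 0), at 4268 and 3251 genes with unadjusted p under 0.05 against 3794. The first of these tests 35077 genes, and the second estimates each gene's spread from 4 degrees of freedom. The cause was not tested for the other settings. Every called gene shared with another setting kept its direction. Where only the blocks, the array weights or the arrays used changed, this was fixed in advance, because no called gene's groups overlapped. The same holds for the called ones among the named genes. Of 1979 comparisons of the 96 named genes with another setting, 1446 kept their side of the threshold, 523 were no longer called, 10 were newly called and 0 reversed. For the gene lists, 294 of 345 kept their side, 37 were no longer called and 13 were newly called. With an estimated correlation 0 of 15 list calls remained (lowest adjusted p 0.103, with 7 lists at unadjusted p under 0.05), and fry kept 10. The remaining 1 was the Hox list, which was not called in the main fit (median -0.02, camera adjusted p = 0.32). Camera called it toward the outer interzone (median 0.35, adjusted p = 0.0459) where signal was required on all 6 arrays, a filter that removes every HoxB gene. The blocks changed no other list call than those given with the lists. Signal over background limits the outer values, since the outer replicate 1 array had the fewest spots above it.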

Other observations

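The tests on cell types other than cartilage, with and without pairing, on scaling, and on the HoxB genes against the other Hox genes and without outer replicate 1 were chosen after the result was seen.

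Several gene families named by a shared symbol stem were lower in the outer interzone. Stems with at least 5 tested members gave 517 families, chosen after seeing the data. The Gimap family of lymphocyte GTPases had 6 of 6 members called, with a median of -2.21 (camera adjusted p = 4.74e-07; adjusted p = 0.998 with an estimated correlation), and the Ms4a family of membrane proteins of B cells, mast cells and macrophages had 4 of 5 called, with a median of -3.61 (camera adjusted p = 0.00229; adjusted p = 0.998 with an estimated correlation). Of 6 genes with the Csf stem, which covers colony-stimulating factors and their receptors, 4 were called lower (median -1.62, camera adjusted p = 0.0151; adjusted p = 0.998 with an estimated correlation), and of 7 insulin-like growth factor binding protein genes, 2 (median -1.25, camera adjusted p = 0.0231; adjusted p = 0.998 with an estimated correlation). Csf1r and Igfbp5 are also in the leukocyte and tendon lists. In the other direction, the Fgfr stem, which holds listed genes (Fgfr1 to Fgfr4) besides Fgfr1op and Fgfr1op2, had 2 of 6 members called higher in the outer interzone, with a median of 0.89 (camera adjusted p = 0.000814; adjusted p = 0.998 with an estimated correlation).

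The split into outer and intermediate interzone called 729 genes, and the highest count among the other splits of the 6 arrays was 0. There are 10 such splits, of which 1 gave as many genes, so the share cannot fall under 0.1 and the design is too small for this test. The 3 other splits that part all same-numbered pairs gave 73, 164 and 110 genes at unadjusted p under 0.05, against 3794 for the real one. The remaining splits, which part 1 pair, gave 299 to 2448. In each split but the real one, the layer difference adds to the spread within groups, which can lower the count. These counts are therefore not a reference for chance.

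Leukocyte and endothelial markers were lower in the outer samples. Low signal of the outer replicate 1 array does not account for it, since without that array the median of both lists was still -2.09, below the bound of -1 set before this test. A scaling pushed down by abundant cartilage transcripts would lower the fibrous tissue genes as well, and these had a median of -0.19. A smaller share of every cell type other than cartilage would lower all their markers alike, but the mean leukocyte and endothelial marker fell further than the mean epidermal marker by -2.85 (95% interval -4.40 to -1.30), or -4.69 to -1.01 with samples paired by replicate number. The gap to erythroid markers (-1.13) included 0 either way (interval -3.85 to 1.59, paired -2.88 to 0.62). The gap to muscle (-1.66) excluded 0 only when paired (interval -4.61 to 1.29, paired -2.54 to -0.78), and the gap to neural markers (-1.52) only when not paired (interval -2.93 to -0.12, paired -3.18 to 0.14). Only the epidermal gap excluded 0 either way, from a list with 10 of 17 genes measured. Its array means were low and varied widely, at -0.22 ± 0.97 (SD, n = 3) in the outer and -0.54 ± 0.78 in the intermediate samples. A smaller share of the other cell types is therefore not excluded. Fewer macrophages and vessels in the outer interzone itself, and tissue taken along with the intermediate samples, both stay open and were not tested, and the abundant members Cx3cr1 and Mrc1 stood at 3.83 and 3.35 in the intermediate samples.

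Same-numbered outer and intermediate samples deviated together, although the labels do not pair them. Replicate 1 was also the dimmest array of each group, with a 75th percentile of 144 (intermediate) and 47.4 (outer). Values near background on the dim arrays do not account for the shared deviation, since among the 4501 brightest genes the correlations were 0.795, 0.627 and 0.508, with the lowest above the 0.1 set before this test. Samples of the same embryo or litter, or samples handled on the same day, may explain it, and the arrays do not separate these.

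HoxB genes were lower in the outer interzone while the other Hox genes were not. The median of the 7 measured HoxB genes was -1.59 and that of the 16 other Hox genes 0.28 (difference -1.87, two-sided permutation p = 0.00036 over 100000 draws, across genes, which are not independent). The HoxB genes were set apart after their low values were seen, so this p-value is no separate support. Among the families, the Hoxb stem had a camera adjusted p = 7.61e-05, but 0.998 with an estimated correlation. The dim outer replicate 1 array does not account for it, since the HoxB median was -1.57 without that array. The filter on dim probes may account for it, because a share of 0.102 of random gene sets with the same number of arrays above background had a median as low, and 95% of such sets lay between -2.09 and -0.06. With normexp, whose offset shrinks the differences of dim genes, the HoxB median was -0.55. A positional difference between the layers was not tested.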
